A study of Glycine max with 12 samples.

How the data were processed

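Roots of soybean (Glycine max) were sequenced as total RNA in 12 libraries, 3 in each of 4 groups that the labels name by inoculum. NM roots had no fungus, Ri roots carried Rhizophagus irregularis, and the other libraries carried Glomus aggregatum at a high (Ga-H) or a low (Ga-L) level of colonization. Per the labels' protocols, RNA was purified with a CTAB-based reagent and ethanol precipitation, and libraries were made with a BGI kit. The labels do not say whether the 3 libraries of a group came from separate plants or pots, so p-values measure the spread between these samples, which may be partly technical. The colonization level itself, plant growth and nutrient contents were not analysed here.

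The authors deposited 1 table per library with an expected count and an FPKM value (fragments scaled to transcript length and library size) for each gene, per the file headers. The submitters' processing notes name Bowtie2, HISAT and RSEM without versions and without saying what each did. Expected counts are estimates in which reads that match several genes or isoforms are divided among them, so near-identical gene copies share reads and their separate values are uncertain. The deposited FPKM values are already divided by library size and gene length. Each table lists only genes above 0, and a gene missing from a library was set to 0 there. The gene IDs carry the soybean annotation tag Wm82.a2.v1. Strand handling and read length are not given in the sources used here.

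The deposited expected counts were rounded to whole numbers before testing. They summed to between 10182200 and 11054762 per library, and the 12 tables together held 49551 genes. Depth was therefore nearly the same in all libraries, and counting intervals and floors given for single genes cover counting error only. A floor of 3 counts per library was used for groups in which a gene had no count. Where a group held 1 to 3 counts of a named gene, the ratio of counts per library total is given with a 95% Clopper-Pearson interval.

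Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with edgeR's default filter by group, which left 36323 genes. Libraries were scaled by TMM, and edgeR's quasi-likelihood test with robust dispersions was fitted to all 12 libraries at once, with 1 mean per group, no replicate block and 8 residual degrees of freedom. The estimated biological coefficient of variation was 22.4%. Each of the 6 pairs of groups was tested as a contrast, and p-values were adjusted over genes by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. The design, the tests and most alternatives were chosen before the data were examined.

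The fit was tested on simulated counts drawn from the means and library sizes of the real genes, with 200 genes changed 2-fold or 4-fold. For Ri against NM it recovered 30% of the 2-fold and 77% of the 4-fold changes, and for Ri against Ga-H, 26% and 65%. Unchanged genes made up 6.1% of the simulated calls for Ri against NM and 5.2% for Ri against Ga-H. These shares hold for the simulated setting, in which 200 of 36323 genes were changed and genes varied independently. The real comparisons with NM called more genes, which loosens the adjusted threshold, so the shares do not estimate their sensitivity. Overlap and correlation between comparisons that share the NM libraries were also computed in 20 simulated data sets with no changed gene.

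The reference table of RefSeq gene names used here belongs to assembly Glycine_max_v4.0. None of its 59048 rows carries an ID of the kind in the deposited tables, so 0 of the 49551 genes could be paired with a symbol, and the table holds no descriptions. The files do not pair IDs with names either. Lists of genes for sugar transport and cleavage, phosphate and ammonium uptake, lipid supply, symbiosis, defence and other functions had been fixed for testing, but with no names they could not be matched, and none of those lists was tested. For the same reason genes are given by ID only, with at most 2 that rose and 2 that fell in each comparison. These were the genes with the largest log2 fold changes among those past the threshold, with a mean of at least 1 FPKM in the higher group and no overlap between the replicates of the compared groups. Where a gene had no count in 1 group, the counts give no finite ratio, so its place in this ranking is uncertain. The planned condition that a gene have an informative description could not be applied.

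Alternatives were RLE size factors, upper quartile scaling, library totals without scaling factors, no low-count filter, the DESeq2 1.42.0 Wald test, limma 3.58.1 with a mean-variance trend on log2(FPKM + 1) for genes with at least 1 FPKM in at least 3 libraries, the same with a pseudocount of 0.1 or without the filter, the replicate number as a block, a fit of the compared groups alone, an added limit of 1 on the absolute log2 fold change, and each replicate left out in turn. Scaling by library totals, and leaving out replicates for the shared gene counts, were chosen after seeing the data. Principal components and library correlations were computed from log2 CPM (counts scaled to library size) of the tested genes with a prior count of 2. No replicate pair had counts that agree within sampling noise, with chi-square per degree of freedom between 6.9 and 42.4, so every library was kept as its own sample. Figures were drawn with matplotlib 3.10.9.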

Results

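Arbuscular mycorrhizal fungi colonize the cortex of plant roots and exchange mineral nutrients, phosphate above all, for sugars and lipids from the plant. To compare how soybean roots respond to different fungal inocula, transcripts were profiled in roots without a fungus (NM), with Rhizophagus irregularis (Ri), and with Glomus aggregatum at high (Ga-H) or low (Ga-L) colonization, with 3 libraries per group. The title of the study places these data in the question of how sugar handling relates to growth benefits from the symbiosis. The total expected count per library ranged from 10182200 in Ga-H replicate 1 to 11054762 in NM replicate 2. A mean of 43018 ± 43 genes (SD, n = 3) was listed with a value above 0 in NM, 43463 ± 410 in Ri, 43666 ± 40 in Ga-H and 43167 ± 195 in Ga-L. Ga-H listed more genes than NM and than Ga-L in every library (2-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 can give).

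The most abundant gene in all 12 libraries was Glyma.09G092700.Wm82.a2.v1, named here after its values were seen. It took 2.64 ± 0.25% of all counts in NM (SD, n = 3), 1.32 ± 0.17% in Ri, 1.22 ± 0.27% in Ga-H and 2.13 ± 0.64% in Ga-L. Its log2 fold change against NM was -1.03 (SE 0.30) in Ri and -1.14 (SE 0.30) in Ga-H, with adjusted p = 0.0428 and 0.0371 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In Ga-L it was -0.26 (SE 0.30), which did not pass (adjusted p = 0.597 in the same edgeR test). Its calls in Ri and Ga-H were both lost with limma on log2(FPKM + 1), with adjusted p = 0.108 and 0.114, and each was lost with 8 of the 12 libraries left out in turn. The Ri call stayed only without Ri replicate 1, Ga-H replicate 1, Ga-L replicate 1 or Ga-L replicate 3, and the Ga-H call only without Ri replicate 1, Ri replicate 2, Ga-L replicate 1 or Ga-L replicate 3, and the edgeR adjusted p reached 0.131 and 0.145. With only the Ri and NM libraries fitted it was 0.0643 for Ri. Over all alternatives the adjusted p ran from 0.000331 to 0.729 in Ri and from 5.35e-05 to 0.783 in Ga-H, the lowest with DESeq2 and the highest with limma without the filter.

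Colonized and uncolonized roots were separated along the first principal component, which held 47% of the variance. The 3 NM libraries had scores from -150.8 to -109.6 and the 9 colonized libraries from 18.8 to 77. The next component, with 16.5% of the variance, placed Ga-L (47.2 to 65.7) apart from Ga-H (-15.3 to -2.6). Ri replicates 2 and 3 lay at -96.3 and -66.2 on it, but Ri replicate 1 lay at 36.8. Across genes, Ri replicate 1 had a mean correlation of 0.908 with the other Ri libraries and 0.948 with the Ga-H libraries.

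**Figure D1:**
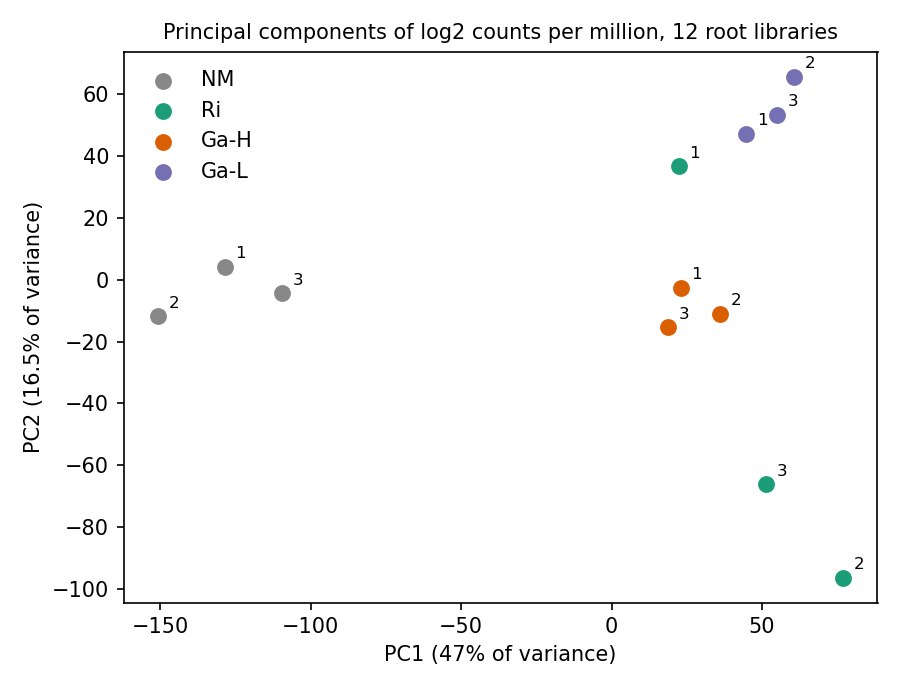
Scores of the 12 root libraries on the first 2 principal components of log2 CPM (counts scaled to library size), with 1 point per library, coloured by group and numbered by replicate. The NM libraries lie at -109.6 or below on PC1 and all colonized libraries at 18.8 or above, and Ri replicate 1 lies at 36.8 on PC2, away from Ri replicates 2 and 3.

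Roots with R. irregularis were compared with uncolonized roots to find the response to this fungus. Of 36323 genes tested, 3297 were higher and 1468 lower in Ri, so 69.2% of the changed genes were higher. This share was 60.1% with upper quartile scaling and 51.9% without Ri replicate 1. The rises were also larger, with 440 genes at a log2 fold change of 5 or more against 15 at -5 or less. The median log2 fold change was 1.5 among genes that rose and -1.02 among genes that fell. These counts are from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. At least a 2-fold change was also seen for 2216 of the higher and 762 of the lower genes.

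The largest rise was that of Glyma.03G012400.Wm82.a2.v1, at 293 ± 291 FPKM in Ri (SD, n = 3) and 0.0433 ± 0.0751 in NM. The NM libraries held 1 count of it in all and the Ri libraries 4980, a ratio of 5150 with a 95% Clopper-Pearson counting interval of 924 to 204000. A single library, Ri replicate 2, held 3480 of these counts, and the ratio without it was 2310. Next was Glyma.03G011600.Wm82.a2.v1 at 163 ± 36.8 FPKM against 0.0433 ± 0.0751, again with 1 count in NM, a ratio of 2880 with an interval of 517 to 114000. Their log2 fold changes were 11.84 (SE 1.25) and 11.00 (SE 0.80), with adjusted p = 0.000116 and 1.22e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The first was 10.66 without Ri replicate 2 and 13.68 without NM replicate 1, which held the only NM count of each gene, so that without it the genes were at least 575-fold and 320-fold higher in Ri against a floor of 3 counts per library. The ratios without NM replicate 2 were 3420 and 1910.

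The deepest fall was that of Glyma.13G252300.Wm82.a2.v1, from 737 ± 433 FPKM in NM (SD, n = 3) to 0.57 ± 0.987 in Ri. Its log2 fold change was -10.31 (SE 2.25, adjusted p = 0.0125 in the same edgeR test), and without Ri replicate 3, which held all its Ri counts, the adjusted p was 0.0536 (0.00011 to 0.0536 over all alternatives) and the gene was at least 1830-fold lower against a floor of 3 counts per library. Glyma.13G251600.Wm82.a2.v1 had 12.7 ± 10.2 FPKM in NM and was not listed in any Ri library, at least 34.8-fold lower against a floor of 3 counts per library. Its call (edgeR adjusted p = 0.03) was lost under DESeq2, where the adjusted p was 0.0776. In edgeR it was lost where only Ri and NM libraries were fitted (0.0845), without the low-count filter (0.0625) and with the replicate number as a block (0.0765). It was also lost without NM replicate 1, NM replicate 3, Ri replicate 2 or Ri replicate 3 (0.0694, 0.0746, 0.066 and 0.073). The adjusted p over all alternatives ran from 0.00576 to 0.0845.

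Single libraries moved the Ri counts. Without Ri replicate 1 there were 5346 higher and 4951 lower genes, without NM replicate 2 there were 1992 higher genes, and the lower genes numbered between 649 and 868 with any of the other 5 libraries left out. When only the Ri and NM libraries were fitted, 1534 genes were higher and 439 lower, and DESeq2 on all libraries called 2263 lower genes.

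Roots with highly colonizing G. aggregatum were compared with NM in the same way. In Ga-H, 2270 genes were higher and 679 lower, and 77% of the changed genes were higher. A log2 fold change of 5 or more was reached by 402 genes and one of -5 or less by 6. Among genes that rose the median log2 fold change was 1.92, and among those that fell it was -1.02. These counts are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The lower genes numbered 1098 with DESeq2, 1394 when only Ga-H and NM libraries were fitted, and 270, 278, 294 and 418 without Ga-H replicate 1, Ga-H replicate 2, NM replicate 1 and NM replicate 3. Without Ri replicate 1 there were 4447 changed genes in all.

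Glyma.03G012400.Wm82.a2.v1 again showed the largest rise, at 144 ± 39.3 FPKM in Ga-H (SD, n = 3). Its log2 fold change was 10.81 (SE 1.27, adjusted p = 0.000243, edgeR), and 2426 counts in Ga-H against 1 in NM gave a ratio of 2540, with a counting interval that started at 455. Without NM replicate 1 it was at least 282-fold higher against a floor of 3 counts per library, and without NM replicate 2 the ratio was 1680. Glyma.03G244400.Wm82.a2.v1 was not listed in any NM library and reached 11.2 ± 6.06 FPKM in Ga-H, at least 74.9-fold higher (adjusted p = 0.00039, edgeR). Glyma.13G251600.Wm82.a2.v1 was not listed in any Ga-H library, at least 34.4-fold lower than in NM (adjusted p = 0.0398, edgeR). This call was lost under DESeq2 (adjusted p = 0.118), with only the Ga-H and NM libraries fitted (0.0603), without the low-count filter (0.0871) and with the replicate number as a block (0.115). It was also lost with 5 of the 6 libraries left out in turn, NM replicate 2 being the exception, and without any of the Ga-L libraries. Its adjusted p ran from 0.00648 to 0.118 over all alternatives. Glyma.15G062800.Wm82.a2.v1 fell from 98.7 ± 65 FPKM in NM to 0.59 ± 1.02 in Ga-H, with a log2 fold change of -7.35 (SE 1.47, adjusted p = 0.00942, edgeR). Without Ga-H replicate 1 its adjusted p was 0.0508 (0.00217 to 0.0508 over all alternatives), its log2 fold change was -6.75 without NM replicate 3, and it was at least 251-fold lower without Ga-H replicate 2, which held all its Ga-H counts.

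In roots with the low level of G. aggregatum colonization, 3188 genes were higher and 1766 lower than in NM, and 64.4% of the changed genes were higher (54.1% with upper quartile scaling). The number of genes that changed against NM was larger in Ga-L, at 4954, than in Ga-H, at 2949, but without Ga-L replicate 2 it was 2504 against 2538. A log2 fold change of 5 or more was found for 481 genes and one of -5 or less for 3. The median log2 fold change was 1.5 among genes that rose and -0.93 among those that fell. These counts are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The higher genes numbered 2090 without NM replicate 2, and the lower genes 344, 371, 565 and 730 without Ga-L replicate 2, NM replicate 2, Ga-L replicate 3 and NM replicate 3. A fit of Ga-L and NM alone gave 3071 lower genes.

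Glyma.03G012400.Wm82.a2.v1 was at 182 ± 47.2 FPKM in Ga-L (SD, n = 3), with 3031 counts against 1 in NM, a ratio of 3220 with a counting interval of 577 to 127000, and its log2 fold change of 11.23 (SE 1.26) had an adjusted p of 0.000123 in edgeR. Without NM replicate 1 it was at least 357-fold higher against a floor of 3 counts per library, and without NM replicate 2 the ratio was 2130. Glyma.06G273200.Wm82.a2.v1 was not listed in any NM library and reached 26.8 ± 9 FPKM in Ga-L, at least 99.4-fold higher (adjusted p = 0.000414, edgeR). Glyma.08G050400.Wm82.a2.v1 had 1.25 ± 1.03 FPKM in NM and was not listed in any Ga-L library, at least 5.16-fold lower (adjusted p = 0.0426, edgeR), and at least 2.8-fold without NM replicate 3. Its call was lost with 5 of the 6 libraries left out in turn, NM replicate 1 being the exception, and without Ri replicate 3 or Ga-H replicate 2. Of the 20 alternatives that gave a value, 8 lost the call, and the adjusted p ran from 0.00204 to 0.115. Glyma.07G038800.Wm82.a2.v1 fell from 28 ± 26.8 to 0.547 ± 0.537 FPKM, with a log2 fold change of -5.56 (SE 0.85, adjusted p = 0.0013, edgeR), which was -4.44 without NM replicate 3 and -6.67 without Ga-L replicate 1.

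**Figure D2:**
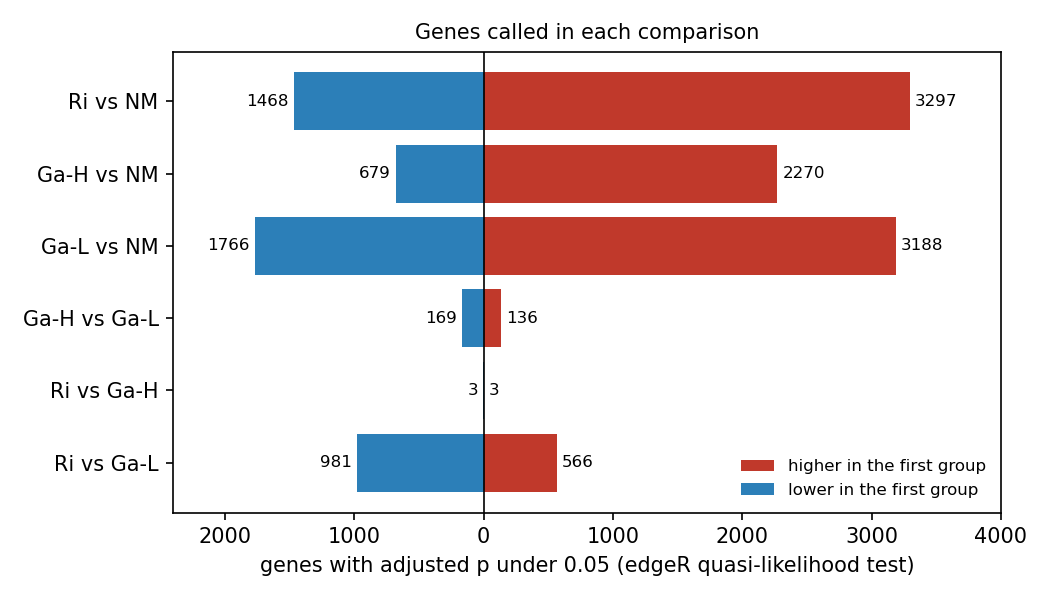
Number of genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test for each of the 6 comparisons, higher in the first-named group to the right and lower to the left. The comparisons with NM have 2270 to 3297 higher genes, and the comparison of Ri with Ga-H has 3 in each direction.

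The 3 colonized groups changed many genes in common against NM. In all 3 comparisons 1635 genes were higher, which is 35.5% of the 4606 genes higher in at least 1. Only 118 genes were lower in all 3, which is 3.9% of the 3043 genes lower in at least 1, and this count was 180 with upper quartile scaling and 203 with DESeq2. It was 58, 43 and 70 without NM replicates 1, 2 and 3, 71 and 57 without Ga-H replicates 1 and 2, 47 without Ga-L replicate 2 and 316 without Ri replicate 1. The median length of the genes higher in all 3 was 1678 bases against 1743 for all tested genes. Their median level was 1.56 FPKM in NM and 12.3 FPKM over the colonized libraries.

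Averaged over those 1635 genes, the level was 1.37 ± 0.29 log2 CPM in NM (SD, n = 3), 4.15 ± 0.12 in Ri, 4.14 ± 0.11 in Ga-H and 4.52 ± 0.19 in Ga-L. The genes were chosen on these libraries, so the gap to NM is not an independent result. NM replicate 3 had the highest level of the NM libraries, 1.71 against 1.26 and 1.16. Among 233 genes that were near absent in the other NM libraries and abundant in all colonized ones, NM replicate 3 held a median of 2.25% of the colonized level. Without this library 1328 genes were higher in all 3 comparisons, against 1320 without NM replicate 1 and 1195 without NM replicate 2. The fall was thus not particular to NM replicate 3.

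**Figure D3:**
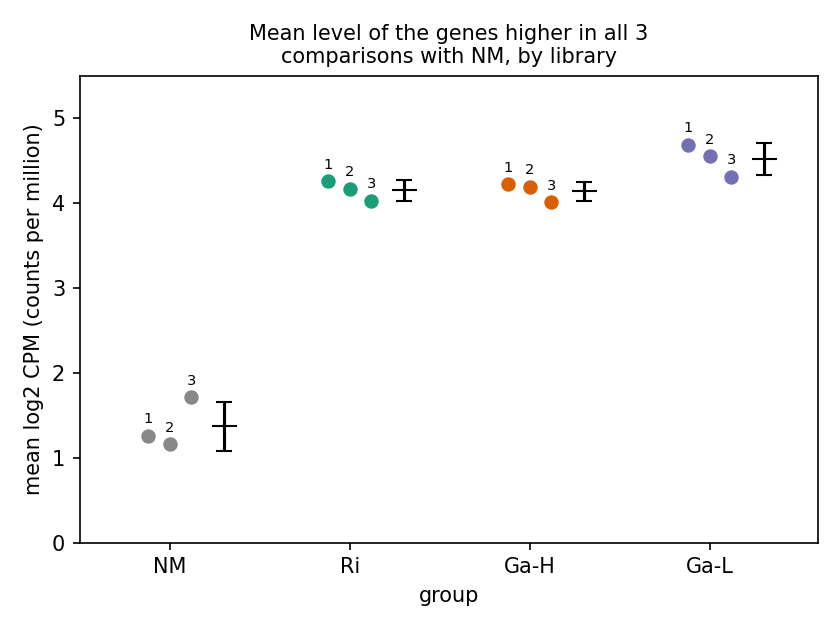
Mean log2 CPM (counts scaled to library size) over the 1635 genes higher in all 3 comparisons with NM, with 1 numbered point per library and the group mean with its SD (n = 3) to the right. NM libraries lie between 1.16 and 1.71, Ri and Ga-H libraries between 4.01 and 4.26, and Ga-L libraries between 4.31 and 4.69.

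By pairs, Ri and Ga-H shared 1862 higher and 473 lower genes, Ri and Ga-L 2003 and 371, and Ga-H and Ga-L 1919 and 144. Independent lists of the same lengths would share 206 and 27, 289 and 71, and 199 and 33. Simulated unchanged groups against the same NM libraries shared at most 0.05 genes on average in 20 draws. With no changed gene almost none is called, so this value was near 0 beforehand. It does not measure how much the common NM libraries add to the sharing between long lists. Across the 36323 genes, which are not independent replicates, the log2 fold changes against NM correlated at r = 0.90 for Ri and Ga-H, 0.83 for Ri and Ga-L and 0.85 for Ga-H and Ga-L, against 0.50 in the simulations. The covariances of 0.99, 1.03 and 0.94 exceeded the simulated 0.06 by 0.93, 0.97 and 0.88. The NM group is too small to be divided, and part of the excess in shared genes may come from the shared NM libraries.

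The direct comparison of Ga-H with Ga-L asked what differs between levels of colonization by the same fungus. It found 136 genes higher and 169 lower in Ga-H by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so 44.6% of the changed genes were higher, against 64.6% when libraries were scaled by their totals alone and 63% with limma on log2(FPKM + 1). Glyma.11G121700.Wm82.a2.v1 was at 4.98 ± 1.89 FPKM in Ga-H and 0.353 ± 0.275 in Ga-L (SD, n = 3), a log2 fold change of 3.81 (SE 0.71, adjusted p = 0.0419, edgeR). Glyma.18G197400.Wm82.a2.v1 was at 2.15 ± 1.01 against 0.147 ± 0.0289 FPKM, a log2 fold change of 3.74 (SE 0.51, adjusted p = 0.0296, edgeR). In the other direction, Glyma.15G082200.Wm82.a2.v1 was at 0.43 ± 0.213 FPKM in Ga-H and 4.94 ± 1.44 in Ga-L (log2 fold change -3.58, SE 0.57, adjusted p = 0.0321, edgeR), and Glyma.10G231600.Wm82.a2.v1 at 1.04 ± 0.206 and 11.2 ± 5.01 (log2 fold change -3.51, SE 0.45, adjusted p = 0.0296, edgeR). The log2 fold change of Glyma.11G121700.Wm82.a2.v1 was 4.57 without Ga-L replicate 1. The calls of all 4 genes were lost without Ga-H replicate 2, Ga-L replicate 2 or NM replicate 3, and some of them without Ga-H replicate 1, Ga-H replicate 3, Ga-L replicate 3 or Ri replicate 3, at edgeR adjusted p from 0.0529 to 0.207. With the replicate number as a block, no gene was called in this comparison, and all 4 genes missed the threshold (edgeR adjusted p from 0.0608 to 0.069). The labels do not say that these numbers mark a pairing. The count of called genes depended on the tool and the libraries, with 952 higher and 1203 lower genes by DESeq2, 1126 and 1339 when only these groups were fitted, 558 and 415 without Ga-L replicate 1, and at most 18 higher and 73 lower genes with any of the other 5 libraries left out. Libraries outside the comparison also moved it, to 1 gene without NM replicate 3 (6793 at an unadjusted p under 0.05 in edgeR), 696 without Ri replicate 2 and 2313 without Ri replicate 1.

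Among the 1919 genes higher than NM in both G. aggregatum groups, most were somewhat lower at the high level of colonization. The median log2 difference of Ga-H from Ga-L was -0.36 (quartiles -0.66 and -0.09), and 18.2% of these genes had the higher value in Ga-H. By edgeR's quasi-likelihood test 6 of the 1919 passed with p adjusted over all tested genes, each lower in Ga-H, and 0 with p adjusted over these genes alone (538 had an unadjusted p under 0.05). With the adjustment over these genes alone DESeq2 called 163, of which 156 were lower in Ga-H, and limma on log2(FPKM + 1) called 0 (456 at an unadjusted p under 0.05). The mean level of the genes higher in all 3 comparisons was above every Ga-H library in every Ga-L library (2-sided exact permutation p = 0.1, the smallest that 3 against 3 can give).

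Few genes separated Ri from Ga-H, roots with fungi of different species, in the direct test. Only 6 of 36323 genes passed edgeR's quasi-likelihood test, 3 in each direction, while 3602 had an unadjusted p under 0.05. Glyma.15G146500.Wm82.a2.v1 was at 16.1 ± 2.98 FPKM in Ri and 2.29 ± 0.36 in Ga-H (SD, n = 3), a log2 fold change of 2.81 (SE 0.36, adjusted p = 0.0402, edgeR). Glyma.12G129500.Wm82.a2.v1 was at 11.7 ± 3.89 against 2.26 ± 0.68 FPKM, a log2 fold change of 2.37 (SE 0.29, adjusted p = 0.0265, edgeR). Glyma.08G141000.Wm82.a2.v1 was lower in Ri, at 9.04 ± 0.845 against 36 ± 3.55 FPKM (log2 fold change -1.98, SE 0.21, adjusted p = 0.0135, edgeR), as was Glyma.15G219400.Wm82.a2.v1, at 3.22 ± 0.738 against 11.3 ± 1.64 FPKM (log2 fold change -1.80, SE 0.18, adjusted p = 0.0135, edgeR). All 4 calls were lost without Ri replicate 3, without Ga-H replicate 1 and without Ga-H replicate 2, and some of them without Ri replicate 2, Ga-H replicate 3, any NM library, Ga-L replicate 1 or Ga-L replicate 2, at edgeR adjusted p from 0.0513 to 0.301. With only Ri and Ga-H libraries fitted, Glyma.08G141000.Wm82.a2.v1 alone of these 4 passed, and limma on log2(FPKM + 0.1) did not call this gene (adjusted p = 0.0514) or Glyma.15G146500.Wm82.a2.v1 (0.0552). The call of Glyma.12G129500.Wm82.a2.v1 was also lost with the replicate number as a block (edgeR adjusted p = 0.072). Without Ri replicate 1, in contrast, 914 genes were higher and 1391 lower in Ri, all 6 genes among them, and DESeq2 on all libraries called 126 and 139 and limma on log2(FPKM + 1) 13 and 29.

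Ri differed from Ga-L in more genes than from Ga-H. There were 566 higher and 981 lower genes in Ri by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 36.6% of the changed genes were higher (50.7% with scaling by library totals alone). Among the 2003 genes higher than NM in both groups, 192 were lower in Ri than in Ga-L and 18 were higher, and the median log2 difference was -0.19 (quartiles -0.65 and 0.11). Glyma.08G181100.Wm82.a2.v1 was at 6.61 ± 5.22 FPKM in Ri and 0.0733 ± 0.0635 in Ga-L (SD, n = 3), where its 2 counts against 206 gave a ratio of 100 with a 95% counting interval of 27.4 to 835 (log2 fold change 6.34, SE 1.13, adjusted p = 0.0163, edgeR), a call lost without Ri replicate 3, Ga-L replicate 2 or Ga-L replicate 3. Glyma.05G011200.Wm82.a2.v1 was at 37.3 ± 57.3 against 0.647 ± 0.734 FPKM (log2 fold change 5.72, SE 1.39, adjusted p = 0.0444, edgeR), but Ri replicate 3 held 720 of its 778 Ri counts, and the log2 fold change was 2.63 without that library and 7.18 without Ga-L replicate 3. Its call was lost with limma on log2(FPKM + 1) (adjusted p = 0.0738), with no low-count filter (0.0734) and with any of the 12 libraries left out except Ri replicates 1 and 2. DESeq2 gave no adjusted p for this gene. Of the 22 alternatives that gave a value, 15 lost the call, and the adjusted p ran from 0.00754 to 0.189. Glyma.13G204600.Wm82.a2.v1 was at 0.17 ± 0.294 FPKM in Ri and 5.72 ± 2.18 in Ga-L (log2 fold change -5.02, SE 0.78, adjusted p = 0.01, edgeR), and Glyma.15G082200.Wm82.a2.v1 at 0.157 ± 0.214 and 4.94 ± 1.44 (log2 fold change -4.98, SE 0.66, adjusted p = 0.00666, edgeR). Without Ri replicate 1 the first was at least 15.1-fold lower against a floor of 3 counts per library and the log2 fold change of the second was -6.98, and with only Ri and Ga-L libraries fitted neither passed (adjusted p = 0.0892 and 0.0747). Without Ri replicate 1 the counts were 2385 higher and 3104 lower. The higher genes numbered 188, 86, 334, 34 and 80 without Ri replicate 2, Ri replicate 3, Ga-L replicate 1, Ga-L replicate 2 and Ga-L replicate 3, and the lower genes 355, 157, 190 and 333 without Ri replicate 2, Ri replicate 3, Ga-L replicate 2 and Ga-L replicate 3. All calls together were 1020 and 1011 without Ga-H replicates 1 and 2. When only Ri and Ga-L libraries were fitted, 2 genes were higher and 8 lower, and DESeq2 on all libraries called 1298 and 1796. With each pair fitted alone, Ga-H against Ga-L had 2465 calls and Ri against Ga-L 10, against 305 and 1547 with all 12 libraries fitted. The order of these comparisons thus reversed. Without Ri replicate 1 the counts were 2313 and 5489, in the original order. That library had a chi-square per degree of freedom of 42.4 and 28.4 with Ri replicates 2 and 3. Call counts thus depended on which libraries were fitted and do not rank the differences between groups.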

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

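The left-out libraries for opposite genes, the tests of shared reads and of a mislabelled library for NM replicate 3, all tests on Ri replicate 1, the rotation test and the value for exchanged labels were chosen after the result was seen. The tests of a small admixture, of scaling and of a single Ga-L library were stated beforehand.

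A small number of genes were called in opposite directions against NM in different inocula. Their direct difference between inocula is the difference of the changes they were picked by. Passing the direct test was therefore likely beforehand and adds little evidence. Some of these genes appear in more than 1 of the comparisons below. For Ga-L, 9 genes were called in the opposite direction from Ri and 9 of them also differed between Ri and Ga-L (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 3 higher in Ri and 6 lower, though 1 of the 9 passed when only Ri and Ga-L libraries were fitted. Between Ga-H and Ga-L there were 3 such genes, all 3 lower than NM in Ga-H and higher than NM in Ga-L, with direct log2 differences of -1.97, -1.70 and -1.30 (adjusted p = 0.0296 each, edgeR). All 3 direct calls were lost without Ga-H replicate 1, Ga-H replicate 2, Ga-L replicate 2, Ga-L replicate 3 or NM replicate 3, and with the replicate number as a block. For Ri and Ga-H, 1 gene was called in opposite directions and did not pass the direct test (adjusted p = 0.0611, edgeR).

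NM replicate 3 held transcripts that were otherwise found in colonized roots. With genes chosen from the other libraries alone, the median share of the colonized level was 2.25% over 233 genes in NM replicate 3, against 0 over 66 genes in NM replicate 1 and 0.186% over 72 genes in NM replicate 2. Reads shared between gene copies, or counting noise, would affect the NM libraries alike, but the share was 12.1 times that of the next NM library, each on its own genes, and a mislabelled colonized library would sit near the full level rather than at 2.25%. The median share was about even over abundant and scarce genes, as a small amount of colonized root, RNA or reads in that library would give. With the genes cut into 3 equal parts, it was 0.876 times as high in the most abundant as in the scarcest. Such material may have entered at any step from pot to sequencing. The medians do not show an even share for each gene. Of the 233 genes, 98.3% had counts in NM replicate 3. Glyma.03G012400.Wm82.a2.v1, named for its large rise, had 0 there but at least 336 in every colonized library. An even share of 2.25% would have given this gene counts in NM replicate 3, so a uniform admixture does not account for it. On a single set of 125 genes chosen by the mean of all 3 NM libraries, the median shares were 1.69% in NM replicate 3, 0.23% in NM replicate 2 and 0.0508% in NM replicate 1, a ratio of 7.35 between the highest and the next, and NM replicate 3 was the highest in 120.

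Ri replicate 1 stood apart from the other Ri libraries, with 1355 genes at least 4-fold from their mean, against 779 and 227 for Ri replicates 2 and 3 and 109 to 356 for libraries of Ga-H, Ga-L and NM, each set against the others of its group. An exchange with a library of another group would leave a partner out of place, but 0 of the 9 libraries outside Ri correlated better with Ri replicates 2 and 3 than with their own group. Depth was alike, at 0.999 times the mean total of the other Ri libraries. Its mean correlation with Ga-H exceeded that with Ri by 0.04. Its correlations with single Ga-H libraries, 0.943 to 0.951, lay below those among Ga-H libraries, 0.965 to 0.970. With Ga-L libraries they were 0.930 to 0.949, below the 0.952 to 0.977 among Ga-L libraries. The Ga-H values argue against a typical Ga-H library under a wrong label. For Ga-L the gap, 0.949 against 0.952, is small beside the range among Ga-L libraries and does not decide. A Ga-L library or an atypical library under a wrong label and a different state of that plant cannot be told apart. A biological difference among Ri roots stays open and untested.

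Genes that rose on colonization were higher in Ga-L than in Ga-H, although the labels give Ga-L the low level of colonization. Over the 1635 genes higher in all 3 comparisons the median log2 difference was 0.38, it was 0.30 under the scaling that lowered it most, and 0.29 with the Ga-L library left out that lowered it most, so neither scaling nor 1 Ga-L library accounts for it. limma's rotation test fry on these genes, which were chosen on these libraries, gave an adjusted p of 0.0548 over 6 tests, which misses the threshold, and each of the 3 Ga-L libraries lay above each Ga-H library. Exchanged group labels and a true difference cannot be told apart, because the labels are the only record of colonization used here and an exchange would only turn the sign of the 0.38.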

How the results depend on the processing

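Scaling by library totals, the left-out replicates for shared and opposite genes and outside a comparison, the adjustment over a gene list alone, the alternatives for the most abundant gene and the counts at unadjusted p were chosen after seeing the data. No named gene reversed direction, but the balance of higher and lower calls turned in Ga-H against Ga-L (136 and 169) under library totals (299 and 164), limma on log2(FPKM + 1) (384 and 226, or 193 and 129 without the filter), a pseudocount of 0.1 (311 and 157) and without Ga-L replicate 1 (558 and 415), and in Ri against Ga-L (566 and 981) under library totals (879 and 855). RLE and upper quartile scaling left the counts of higher and lower genes in the 6 comparisons and in all 3 comparisons with NM within 1.5 times the main value, except 180 genes lower in all 3 under upper quartile scaling (118), and the median log2 fold change of all genes stayed between -0.062 and 0.101 under the 4 scalings. Causes of single shifts were not tested.

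With DESeq2 there were 2263 lower genes in Ri against NM (1468 by edgeR), 1098 lower in Ga-H against NM (679), 952 higher and 1203 lower in Ga-H against Ga-L (136 and 169), 126 and 139 in Ri against Ga-H (3 and 3), 1298 and 1796 in Ri against Ga-L (566 and 981), and 203 genes lower in all 3 (118). When only the compared groups were fitted, there were 1534 and 439 in Ri against NM (3297 and 1468), 1394 lower in Ga-H against NM, 3071 lower in Ga-L against NM (1766), 1126 and 1339 in Ga-H against Ga-L, 0 and 2 in Ri against Ga-H (2503 genes at unadjusted p under 0.05 in edgeR), and 2 and 8 in Ri against Ga-L. A limit of 1 on the absolute log2 fold change left 39 genes lower in all 3, 762, 352 and 814 lower genes in the comparisons of Ri, Ga-H and Ga-L with NM, 75 and 103 in Ga-H against Ga-L, and 343 and 638 in Ri against Ga-L. limma on log2(FPKM + 1) gave 13 and 29 in Ri against Ga-H (17 and 23 without the filter), and 1 higher gene there with a pseudocount of 0.1. Without the low-count filter Ri against Ga-H had 5 and 7.

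With the replicate block, Ga-H against Ga-L had 0 higher and 0 lower genes in edgeR, with 6918 at unadjusted p under 0.05, so that its 4 named genes (adjusted p = 0.069, 0.0658, 0.0658 and 0.0608, edgeR) and the 3 genes moving in opposite directions were not called, Ri against Ga-H had 4 calls in all, and every other count stayed within 1.5 times. The labels share replicate numbers without saying that these mark a pairing. Of the 18 same-number pairs of libraries, 6 had deviations that correlated above 0.1 (range -0.40 to 0.23), all 6 among the 9 pairs of colonized groups, where 8 were above 0, and the pairs with NM reached at most 0.08. For Ga-H and Ga-L the values were 0.22, 0.15 and 0.04. As not every pair exceeded 0.1 and 5 of the 12 libraries were closest to their own number, the numbers were not taken to pair the samples. A pairing among the colonized groups alone stays possible.

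With single replicates of the compared groups left out, the higher and lower genes ranged from 1992 to 5346 and 649 to 4951 in Ri against NM, 1518 to 1981 and 270 to 598 in Ga-H against NM, 2090 to 3114 and 344 to 2431 in Ga-L against NM, 0 to 558 and 0 to 415 in Ga-H against Ga-L, 0 to 914 and 0 to 1391 in Ri against Ga-H, and 34 to 2385 and 157 to 3104 in Ri against Ga-L. With any of the 12 libraries left out, genes higher in all 3 ranged from 1195 to 1982 and lower in all 3 from 43 to 316. The highest counts in the comparisons with Ri came without Ri replicate 1, and libraries outside a comparison also moved its calls, in Ga-H against Ga-L from 305 to 2313 without Ri replicate 1, 696 without Ri replicate 2 and 1 without NM replicate 3 (6793 at unadjusted p under 0.05), in Ga-H against NM from 2949 to 4447 without Ri replicate 1, and in Ri against Ga-L from 1547 to 1020 and 1011 without Ga-H replicates 1 and 2. In edgeR, 0 genes were called for Ga-H against Ga-L without Ga-H replicate 2 or Ga-L replicate 2 (6582 and 4664 at unadjusted p under 0.05) and for Ri against Ga-H without Ri replicate 3, Ga-H replicate 1 or Ga-H replicate 2 (2643, 2197 and 3045). The named rises against NM stayed past the threshold under RLE, DESeq2, limma, the block and each left-out replicate.

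Each comparison of 3 against 3 has 10 splits of its libraries, too few for a share under 0.05, and in each the real split was the 1 with the most calls. Every other split mixes the groups, so their difference adds to the spread within groups, and few calls were likely beforehand. The real counts were 4765, 2949, 4954, 305, 6 and 1547 for Ri, Ga-H and Ga-L against NM, Ga-H against Ga-L, Ri against Ga-H and Ri against Ga-L, and the highest of the other splits 0, 0, 0, 0, 4 and 1. The tests of the fixed gene lists, with their alternatives for correlation, block, scaling and left-out replicates, were not run because no list could be matched to the IDs.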

Other observations

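The rotation test and the single genes below were chosen after the result was seen, and the test of neighbouring IDs was stated beforehand.

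Some genes were detected only with a fungus, by the measures below. At least 1 FPKM in all 9 colonized libraries and an FPKM of 0 in every NM library was found for 19 genes, 3 of them with at least 5 FPKM throughout, and the reverse for 0 genes. By group, 31 genes were at 1 FPKM or more in all Ri libraries and had counts that rounded to 0 in all NM libraries. There were 30 such genes for Ga-H and 43 for Ga-L, and 4, 3 and 3 genes in the reverse direction. Other splits of the same 6 libraries, which mix the groups, gave at most 3, 3 and 5 such genes. The reverse counts for Ga-H and Ga-L did not exceed these. Chance alone separates 3 libraries from 3 in 10% of genes whose values carry no ties. That rate does not apply to the genes counted here, which are tied at 0 in 1 group.

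Glyma.13G252300.Wm82.a2.v1, the gene with the deepest fall in Ri, stood at 737 ± 433 FPKM in NM (SD, n = 3), 66.3 ± 98.5 in Ga-L (9.68 without Ga-L replicate 2), 11.5 ± 16.9 in Ga-H (1.7 without Ga-H replicate 2) and 0.57 ± 0.987 in Ri, where only Ri replicate 3 had counts of it. Without Ga-L replicate 1 the Ga-L mean was 99.4, and without Ri replicate 1 or 2 the Ri mean was 0.855. The log2 fold changes of -6.03 (SE 1.72) in Ga-H and -3.43 (SE 1.5) in Ga-L did not pass (adjusted p = 0.057 and 0.151 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and neither did the direct differences of Ri from Ga-L, at -6.89 (SE 2.12, adjusted p = 0.0928), of Ri from Ga-H (adjusted p = 0.54) or of Ga-H from Ga-L (adjusted p = 0.363, all edgeR).

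A hypothesis was that genes that rise with colonization have neighbouring ID numbers. Of the 1635 genes higher in all 3 comparisons, 1623 have IDs numbered along 1 of 20 series, and they formed 183 pairs adjacent among the tested IDs, against a mean of 73.5 and a highest value of 116 in 1000 shuffles. In all, 20.3% of them had such a neighbour, and the longest run held 5. The 118 genes lower in all 3 formed 3 adjacent pairs, against a mean of 0.4 and a highest value of 3. The excess of 183 pairs is consistent with groups of neighbouring genes that rise together, and reads shared between similar adjacent copies remain a possible explanation that was not tested.

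The mean level of the 118 genes lower in all 3 comparisons was 5.06 ± 0.03 log2 CPM in NM (SD, n = 3), 3.67 ± 0.11 in Ri, 3.8 ± 0.15 in Ga-H and 3.96 ± 0.11 in Ga-L. These genes were chosen on these libraries for being lower than NM, so the gap to NM is not an independent result. limma's rotation test fry for a lower level in Ri than in Ga-L gave an adjusted p of 0.0548 over 6 tests, which misses the threshold.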
